A study of Arabidopsis thaliana with 15 samples.

How the data were processed

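The experiment measured transcript levels in whole seedlings of Arabidopsis thaliana, ecotype Columbia, on Affymetrix ATH1 arrays, which carry sets of short probes for most genes of the plant. Seedlings grew on vertical plates with MS medium (a standard plant nutrient medium) and sucrose under continuous light at 22 °C. On day 5 they were moved to plates with 10 µM estrogen, or to new plates without it for the controls, and collected after 4 h or 48 h. In the induced seedlings, estrogen switched on either FAMA, a basic helix-loop-helix transcription factor that acts late in the formation of guard cells, the paired cells around each stomatal pore, or FAMA-EAR, the same protein fused to the EAR repression domain. Harvests were frozen until there was enough material, RNA was isolated with a silica column kit, and biotin-labelled cRNA was prepared with a commercial transcript labelling kit.

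The deposited values are MAS5 signal intensity on a linear scale, with 1 value for each of 22810 probe sets on each of 15 arrays. MAS5 is named in the submitters' processing notes, without a version. The mean of each array after removal of the lowest and highest 2% of probe sets lay between 500.04 and 500.048, so the authors scaled all arrays to a common level. The scaling target, the software version and the probe annotation are not given in the sources used here. MAS5 reads each array alone and subtracts mismatch probes, so low signals carry a larger relative error than high ones, and a scaling to a common mean can move many genes together when abundant transcripts change. Detection calls and raw probe values were not used here. The files hold no counts, so the number of arrays limits the precision.

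Samples were placed in 5 groups of 3 arrays from their titles, namely control 4 h, control 48 h, FAMA 4 h, FAMA 48 h and FAMA-EAR 48 h. The labels do not say whether the 3 replicates of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical. Controls had no estrogen, so every comparison with a control holds the estrogen treatment and the construct together. The comparison of FAMA 48 h with FAMA-EAR 48 h does not, because both had estrogen for the same time.

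The design, the gene lists, the rule for named genes and the alternatives described next were fixed before the data were examined, except where stated. Signals were transformed as log2(signal + 20), where the offset is the median of all deposited signals, 197.4, divided by 10 and rounded. The 64 control probe sets were left out and 22746 probe sets were tested in limma 3.58.1 under R 4.3.3, in 1 fit with a mean for each group and 10 residual degrees of freedom. Variances were moderated with a trend on the mean, tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all tested probe sets with a threshold of 0.05. All adjusted p-values of genes below are from this limma fit, and standard errors (SE) of log2 fold changes use its moderated variances. With 3 arrays against 3, an exact two-sided test of a single gene cannot go below p = 0.1. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

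Gene names came from a table that pairs probe sets with genes, matched to a reference gene table of assembly TAIR10.1, which also gave the coordinates. That table covered 14016 probe sets, of which 13513 named 1 gene and 503 named several, while 8730 of the tested probe sets had no gene name. Of the probe sets with 1 gene, 13436 were found in the reference table. Counts of changed probe sets use all 22746, and gene names are limited to those with 1 gene. FAMA itself is named FMA in the table and is called FAMA here.

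Of 21 gene lists fixed in advance, 5 had at least 3 members with a named probe set and were tested, and 16 were not tested. The lists held 337 different genes, and 39 had a named probe set. The tested lists were stomatal lineage regulators, guard cell genes, genes of the G2 and M phases of the cell cycle, photosynthesis genes and early auxin response genes. In that order, 3 of 21, 4 of 24, 3 of 25, 5 of 36 and 7 of 14 listed genes had a named probe set. Members called measured below are these, and the other listed genes could not be read. Each gene was represented by its probe set with the highest mean. Lists were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, and p-values were adjusted over the lists within a comparison. After the probe annotation and the largest changes had been seen, 31 further sets were tested in the same way, namely families of genes for 30 symbol prefixes with at least 8 measured members each, and 16 mitochondrial genes. The prefixes EXP and EXPA held the same genes, so 29 families differed. Groups of plastid-encoded genes and of genes induced by iron deficiency were added after their members had been seen among the changed genes.

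The named genes were FAMA first, then the 12 largest rises and 12 largest falls among probe sets that named 1 gene. These had to pass the threshold, to have all 3 arrays of a group above all 3 of the other, and to have a higher group with a mean signal of at least the overall median. For the difference between times the rule took 6 genes in each direction, with the separation of arrays taken from the 48 h groups. The text names a part of them. Chance alone separates 3 arrays from 3 in 10% of probe sets, and the observed share was 17.4% for FAMA at 4 h, 39.7% for FAMA at 48 h and 22.2% for FAMA-EAR. Up to 4 members of each list were named besides.

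The fit was tested on simulated data with 22746 probe sets, of which 100 were changed by 1 log2 unit and 100 by 2. With equal spread on all arrays it recovered 64% of changes of 1 log2 unit and 99% of changes of 2 log2 units for FAMA at 4 h, 68% and 99% for FAMA at 48 h, 66% and 99% for FAMA-EAR and for the controls over time, 64% and 98% for FAMA against FAMA-EAR, and 45% and 94% for the difference between times. False calls made up between 3.47% and 6.78% of the calls. With each array's own spread taken from its residuals, the share of false calls for FAMA at 4 h was 17%. Under that noise it was 20.7% without the third FAMA 4 h array and 8.54% in a fit with array weights. A noise model with spreads from limma array weights was added after the 17% had been seen, and gave 7.36%. A simulated list of 5 genes lowered by 0.7 log2 units at 48 h was called lower by camera, and 6 of 200 unshifted lists had an unadjusted p under 0.05. The simulated genes varied independently, so this says nothing about false calls for lists whose genes vary together.

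Alternatives covered the offset, a floor on low signals, a filter at the 40th percentile, quantile normalization, equal array medians, no variance trend, array weights, a fit of only the groups compared, replicate number as a block, a test without moderation, a 2-fold threshold, other list tests, and each array left out in turn. The third array of FAMA 4 h differed from the rest, so results were also computed without it, as an alternative chosen after seeing the data.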

Results

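The series holds 15 arrays in 5 groups of 3, and covers whole seedlings 4 h and 48 h after transfer, with no induction or with estrogen-induced FAMA, and seedlings 48 h after induction of FAMA-EAR. Seedlings were 5 days old at 4 h and 7 days old at 48 h. The median signal per array lay between 188.2 and 199 on 14 arrays. On the third array of FAMA 4 h it was 239.5, with a lower quartile of 79.2 against 39.7 to 48.1 on the others. Mean rank correlations with the other arrays of a group lay between 0.953 and 0.985, except for that array, with 0.929.

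The induced gene was read first in every sample. FAMA (AT3G24140, TAIR10.1 chromosome 3, 8715118 to 8718211) had a signal of 245.9 ± 13.7 (SD, n = 3) in the 4 h controls and 243.5 ± 12.9 (SD, n = 3) in the 48 h controls. It reached 12377 ± 601 (SD, n = 3) after 4 h of FAMA induction and 18024 ± 944 (SD, n = 3) after 48 h. In FAMA-EAR seedlings it was 3060 ± 369 (SD, n = 3), below every FAMA 48 h array. The log2 fold change over the control was 5.54 at 4 h (SE 0.0875, adjusted p = 1.81e-20), 6.10 at 48 h (adjusted p = 2.63e-21) and 3.54 for FAMA-EAR (adjusted p = 1.52e-16). Every induced array lay above every control array.

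**Figure D1:**
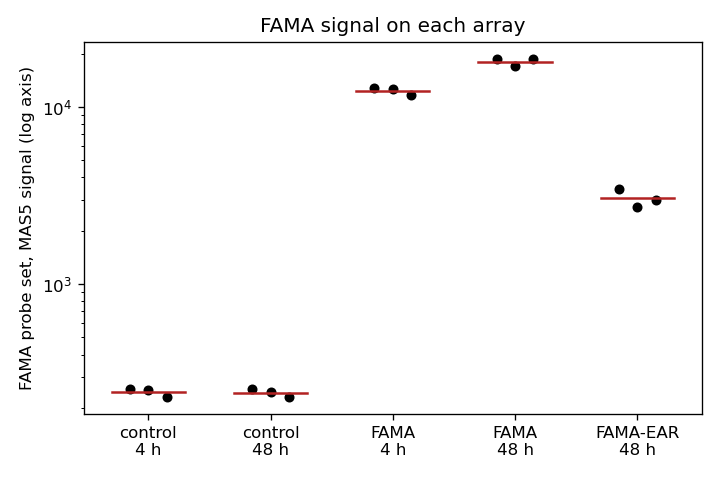
Deposited MAS5 signal of the FAMA probe set on each array (log axis), with 1 point per array and a line at the mean of each group of 3. The 6 control arrays lay between 229.6 and 255.7, and the FAMA-EAR arrays lay between the controls and the FAMA arrays.

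The comparison of FAMA with control seedlings at 4 h asked which transcripts changed early after induction. AT2G40435 rose by 2.1 log2 units (SE 0.215, adjusted p = 8.78e-06), from a signal of 41.4 ± 11 to 243.3 ± 45.8 (SD, n = 3 each). Its control signal was low, so the size of this change depends on the offset. Among the other large rises, the polygalacturonase gene AT1G48100 (PGX3) rose by 1.74 (SE 0.163, adjusted p = 4.03e-06), and AT3G17130, which encodes a protein of the invertase and pectin methylesterase inhibitor family, rose by 1.58 (SE 0.162, adjusted p = 8.94e-06). AT1G70820, annotated as a phosphoglucomutase, rose by 1.41 (SE 0.136, adjusted p = 4.45e-06). ICL, the isocitrate lyase of the glyoxylate cycle, had a log2 fold change of -2.12 (SE 0.415, adjusted p = 0.0056), a call that ended without the second 4 h control (adjusted p = 0.0553) and when only these 6 arrays were fitted (adjusted p = 0.0563). The class III peroxidase genes AT1G30870 and AT4G26010 fell by 1.86 (SE 0.233, adjusted p = 1e-04) and 1.64 (SE 0.191, adjusted p = 4.59e-05).

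Of the 22746 probe sets, 261 were higher and 403 lower after 4 h, 664 in all. The median log2 fold change of all probe sets was 0.09 in this comparison, and with array medians set equal 111 were higher and 451 lower. Without the third FAMA 4 h array, 255 were higher and 344 lower. The count was 342 without the third 4 h control, 398 without the second, and 1077 without the second FAMA 4 h array. It was 303 with no variance trend, 207 when only these 6 arrays were fitted and 2 with a test without moderation. None of the 5 gene lists shifted: 0 passed with camera, 0 had an unadjusted p under 0.05 with camera, and 0 passed with fry. The guard cell list of 4 genes had a median of 0.21 (adjusted p = 0.76), and SPCH and MUTE, the bHLH factors that act before FAMA in the lineage, had log2 fold changes of -0.39 (SE 0.193, adjusted p = 0.314) and -0.23 (SE 0.425, adjusted p = 0.808). The RPS family, mostly ribosomal protein genes of the plastid, had a median of -0.18, with 0 of 9 members past the threshold (limma). Its adjusted p was 0.0125, and the adjusted p was 0.979 with an estimated correlation and 0.318 after quantile normalization.

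At 48 h the same comparison asked which transcripts had changed after longer induction, and the changes were larger. AT2G34810, of the berberine bridge enzyme-like family (chromosome 2, 14685170 to 14687216), rose by 5.07 log2 units (SE 0.118, adjusted p = 2.21e-17), from 190.1 ± 8.99 to 7069 ± 842 (SD, n = 3 each). The expansin gene EXPA16 (chromosome 3, 20574752 to 20576249) rose by 4.86 (SE 0.145, adjusted p = 1.38e-15) and AT3G57600, an AP2/ERF transcription factor gene, by 4.63 (SE 0.223, adjusted p = 3.33e-12). The cytidine deaminase gene AT4G29570 and AT4G36700, of the cupin family, rose to 832 and 1188 from control signals of 9.07 and 25.8, near background, so the size of their change depends on the offset. The acyltransferase family gene AT4G15390 fell by 2.2 (SE 0.207, adjusted p = 8.41e-08), and AT5G14120, of the major facilitator transporters, fell from 5085 ± 796 to 1572 ± 95.5 (SD, n = 3 each). The mean log2 ratio of 3' to 5' probe sets for actin and GAPDH, a sign of RNA degradation, was 0.199, 0.191 and 0.214 on the FAMA arrays, below each 48 h control at 0.301, 0.496 and 0.297, so this comparison also parts the arrays by that ratio. The 5' actin signal was 9056.9 to 9919.5 on the FAMA arrays and 5601.4 to 6018 on these controls, and GAPDH alone did not part the groups.

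Guard cell genes rose at 48 h of FAMA. Of 4 measured members, 3 rose and PME6 had a log2 fold change of 0.34 (SE 0.246, adjusted p = 0.404); the list's median was 0.95 (adjusted p = 0.00014, and 0.0322 with an estimated correlation). GC1 (AT1G22690, chromosome 1, 8027126 to 8028168), whose promoter is a common guard cell marker, rose by 1.83 (SE 0.107, adjusted p = 7e-11), from 3015 ± 223 to 10802 ± 1330 (SD, n = 3 each). CHX20, a cation exchanger of guard cells, rose by 0.98 (SE 0.179, adjusted p = 0.000302), and BLUS1 (AT4G14480), a kinase of blue light signalling in guard cells, rose by 0.92 (SE 0.192, adjusted p = 0.0011).

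The stomatal lineage list was lower, through SPCH and STOMAGEN. Of 3 measured members besides FAMA, 2 fell, and the median was -0.76 (adjusted p = 0.0072, and 0.0322 with an estimated correlation). SPCH (chromosome 5, 21586219 to 21589255), which starts the lineage, fell by 0.76 (SE 0.193, adjusted p = 0.00573), and STOMAGEN (EPFL9), a mesophyll peptide that raises stomatal number, fell by 0.83 (SE 0.107, adjusted p = 5.64e-06). MUTE had a log2 fold change of -0.65 (SE 0.425, adjusted p = 0.344), at signals of 39.6 in the controls and 15.5 after FAMA. Of 25 listed G2 and M phase genes, only the 3 Aurora kinase genes had a named probe set. Of these 3, 2 fell (median -0.56, adjusted p = 0.0143, and 0.0358 with an estimated correlation). AUR1 fell by 0.56 (SE 0.122, adjusted p = 0.00187). AUR3 fell by 0.71 (SE 0.209, adjusted p = 0.0162), a call that ended without the second FAMA 48 h array (adjusted p = 0.0732) or the second 48 h control (adjusted p = 0.0512).

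The measured nuclear genes of photosynthesis, 5 of 36 listed, fell together. All 5 passed the threshold, with a median of -0.67 (adjusted p = 5.66e-06, and 0.0322 with an estimated correlation). PSAN, a photosystem I subunit, fell by 1.11 (SE 0.1, adjusted p = 4.69e-08), LHCB4.1, a light-harvesting protein, by 0.72 (SE 0.104, adjusted p = 2.13e-05), and SBPASE, of the Calvin cycle, by 0.67 (SE 0.0865, adjusted p = 5.17e-06). RCA, the Rubisco activase, fell by 0.51 (SE 0.0974, adjusted p = 0.000494). All 5 were among the brightest probe sets, and the 230 other probe sets at least as bright had a median of -0.31, with 136 lower and 5 higher. PYK10, an abundant root beta-glucosidase, fell by 0.68 (SE 0.0962, adjusted p = 1.76e-05). After quantile normalization the median of the photosynthesis list was -0.41 (adjusted p = 0.000704), and RCA no longer passed (-0.05, adjusted p = 0.727). That of the other bright probe sets was -0.02, a value this normalization sets near 0 by construction, so it is no independent background for the list.

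Among 7 early auxin response genes 3 fell, with a list median of -0.49 (adjusted p = 0.0203, and 0.0492 with an estimated correlation). GH3.5 (WES1), which conjugates auxin to amino acids, fell by 0.82 (SE 0.108, adjusted p = 7.25e-06), GH3.3 by 0.85 (SE 0.219, adjusted p = 0.00677) and IAA29 by 0.79 (SE 0.235, adjusted p = 0.0182). GH3.3 no longer passed without the second 48 h control (adjusted p = 0.0554). IAA29 no longer passed without the second or the third 48 h control (adjusted p = 0.0756 and 0.0596), without the first FAMA 48 h array (adjusted p = 0.1) or with the median divided by 2 as the offset (adjusted p = 0.0565). Counts adjusted over the list alone were 2, 3, 2, 5 and 3 for the stomatal lineage, guard cell, cell cycle, photosynthesis and auxin lists, as over all probe sets. In the XTH family of xyloglucan-modifying wall enzymes, XTH16, XTH32 and XTH19 rose by 1.51, 1.57 and 1.36 and EXGT-A3 fell by 0.33, while 6 of 10 members did not pass. The family's adjusted p was 0.0136, and the adjusted p was 0.185 with an estimated correlation. Of 11 genes of the autophagy family ATG, 5 rose, among them ATG8B by 0.88, and ATG8E fell by 0.48 (adjusted p = 0.0136 for the family, and adjusted p = 0.397 with an estimated correlation). In all, 2409 probe sets were higher and 2504 lower, 4913 of 22746, and 851 of these changed at least 2-fold.

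**Figure D2:**
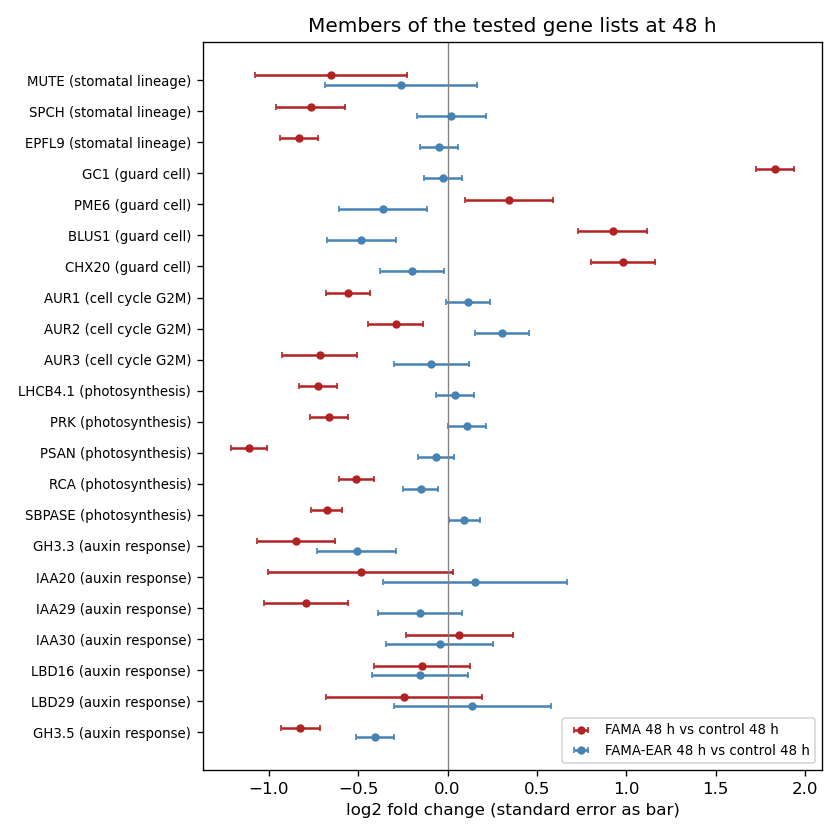
Log2 fold change over the 48 h controls of each measured member of the 5 tested gene lists, for FAMA (red) and FAMA-EAR (blue), with the standard error of the limma fit as bars and 3 arrays per group. GC1 stood at 1.83 with FAMA and at -0.02 with FAMA-EAR, and 5 of 5 photosynthesis genes lay below 0 with FAMA.

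The test of the difference between times asked whether the FAMA effect at 48 h departed from that at 4 h, and 3103 probe sets passed, 1500 with a higher and 1603 with a lower effect at 48 h. The median difference of all probe sets was -0.14, and the differences given here for named genes are relative to it, while their tests are of the differences themselves. AT2G34810 differed by 4.80 (SE 0.167, adjusted p = 2.4e-13) and EXPA16 by 4.28 (SE 0.205, adjusted p = 2.38e-11). AT1G70820, higher at 4 h and lower at 48 h, differed by -2.78 (SE 0.192, adjusted p = 1.91e-09), and AT1G66100 by -2.21 (SE 0.197, adjusted p = 5.6e-08). FAMA itself differed by 0.69 (SE 0.124, adjusted p = 0.0038). With array medians set equal, 1444 were higher and 964 lower. The peroxidase genes AT1G30870 and AT4G26010, lower at 4 h, were higher at 48 h by 1.07 and 0.98, and the tests of their difference gave adjusted p = 2.7e-06 and 9e-07.

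Of the gene lists, 3 differed between the times with the preset correlation, namely guard cell genes (median 0.66, adjusted p = 0.000777), G2 and M phase genes (median -0.71, adjusted p = 0.0319) and photosynthesis genes (median -0.66, adjusted p = 0.000166). Each had an adjusted p of 0.0659 with an estimated correlation. Of their members, 1 of 4 guard cell genes rose (2 adjusted over the list alone), 2 of 3 G2 and M phase genes fell (2 adjusted over the list alone) and 5 of 5 photosynthesis genes fell (5 adjusted over the list alone). With equal array medians PRK, RCA and SBPASE no longer passed (adjusted p = 0.23, 0.0987 and 0.149), nor did PRK and RCA after quantile normalization (adjusted p = 0.152 and 0.472). The PRK call also ended with a floor (adjusted p = 0.0598), with no variance trend (adjusted p = 0.0896) and on leaving out any 1 of 4 arrays (adjusted p = 0.0533 to 0.0665). After quantile normalization the median of the photosynthesis list was -0.37 (adjusted p = 0.00317). The XTH family also differed (median 0.94, adjusted p = 0.000354, and 0.0312 with an estimated correlation), and XTH19, a member, fell by 0.58 at 4 h and rose by 1.36 at 48 h. Across probe sets, which are not independent replicates, the effects at 4 h and 48 h had a Pearson correlation of 0.04 and a Spearman correlation of -0.001. The Pearson value was -0.03 at an offset of 1, 0.14 above the 40th percentile, and 0.02 to 0.07 with 1 array left out. The 2 comparisons shared 69 probe sets higher in both, where independent lists would share 27.6, and 197 lower in both, against 44.4. A further 71 were higher and then lower, against 28.7, and 33 were lower and then higher, against 42.7. Calls at both times used the same variance for each probe set, so independent lists are no exact measure for unrelated effects.

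FAMA-EAR was compared with the same 48 h controls to see what changed when FAMA carried a repression domain. The 12 largest falls that the rule named were all plastid-encoded. They included accD (a subunit of acetyl-CoA carboxylase, plastid genome 57075 to 58541), with a fall of 2.27 log2 units (SE 0.171, adjusted p = 9.61e-08), from 1115 ± 108 to 221.7 ± 74.8 (SD, n = 3 each). The ATP synthase gene atpA fell by 2.03 (SE 0.196, adjusted p = 2.49e-06), psaA of photosystem I by 1.95 (SE 0.261, adjusted p = 0.000117) and rbcL, the large subunit of Rubisco, by 1.64 (SE 0.246, adjusted p = 0.000423). Among the rises, AT1G43590 (adjusted p = 5.92e-07) and QQS, a gene that affects starch content (adjusted p = 2.8e-05), reached 407 and 405 from control signals of 15.8 and 26.0, so the size of their change depends on the offset.

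Of 69 genes of the plastid genome, a group chosen after these falls had been seen, 45 fell and 0 rose with FAMA-EAR (limma), and 52 fell and 3 rose adjusted over the list alone. The median was -0.98, and -0.95 after quantile normalization. No test of the group is given for comparisons with these arrays, since it would restate the falls that led to it. The mean log2 ratio of 3' to 5' probe sets for actin and GAPDH was 0.558, 0.731 and 0.533 on the FAMA-EAR arrays, above each control 48 h and FAMA 48 h array. With FAMA at 48 h the plastid median was -0.14, with 2 higher and 3 lower. In the RPS family, most of whose genes belong to this group, 6 of 9 fell with FAMA-EAR. Its camera test (adjusted p = 0.000708, and adjusted p = 0.653 with an estimated correlation) therefore restates these falls and adds no separate support.

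**Figure D3:**
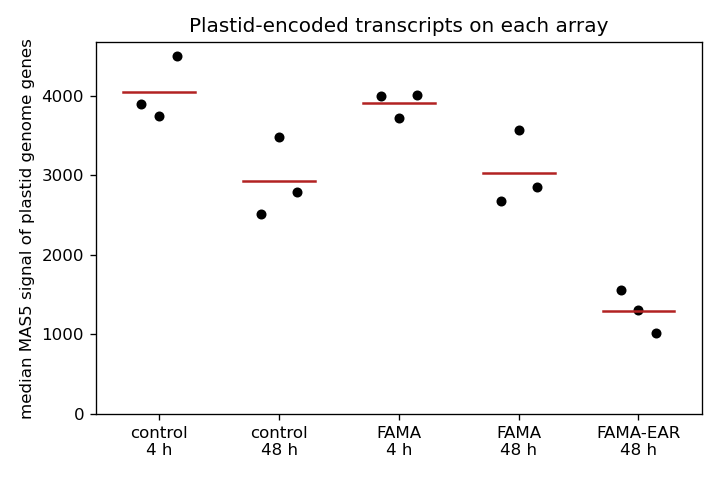
Median MAS5 signal of the 69 plastid genome genes on each array (linear axis from 0), with 1 point per array and a line at the mean of each group of 3. The FAMA-EAR arrays read 1556, 1304 and 1017, below the 48 h controls at 2510, 3477 and 2788.

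None of the 5 fixed lists shifted with FAMA-EAR: 0 passed with camera, 0 had an unadjusted p under 0.05, and 0 passed with fry. The photosynthesis list had a median of 0.04 (adjusted p = 0.921) and the guard cell list -0.28 (adjusted p = 0.273), with GC1 at -0.02 (SE 0.107, adjusted p = 0.965) and BLUS1 at -0.48 (SE 0.192, adjusted p = 0.214). SPCH stood at 0.02 (SE 0.193, adjusted p = 0.987). GH3.5 (WES1) was the 1 member of the lists that fell (-0.41, SE 0.108, adjusted p = 0.0425), a call that did not hold: it ended without any 1 of the 6 arrays compared (adjusted p = 0.0661 to 0.143), with equal array medians (adjusted p = 0.0755), after quantile normalization (adjusted p = 0.0537) and with no variance trend (adjusted p = 0.114). GSTU25, a glutathione transferase gene, fell by 1.01 (SE 0.116, adjusted p = 1.68e-05). In the ATG family ATG8C rose by 0.45, and the family had a median of 0.15 (adjusted p = 0.00427, and adjusted p = 0.653 with an estimated correlation).

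In all, 317 probe sets were higher and 412 lower with FAMA-EAR, 729 of 22746. The count was 1176 without the third FAMA 4 h array, 358 to 473 without any 1 of the FAMA-EAR arrays, 399 and 387 without the second and the third 48 h control, and 463 with equal array medians. It was 322 with no variance trend, 1217 with array weights and 0 with a test without moderation. Effects of FAMA and FAMA-EAR over the shared controls had a Pearson correlation of 0.25 and a Spearman correlation of 0.29 across probe sets, where shared controls alone gave 0.50 and 0.46 in simulations. A correlation shrinks as real effects add variance, and the covariance was 0.0424, against a simulated mean of 0.0374 and a highest simulated value of 0.0391. The simulations drew probe sets independently, so their range leaves out errors shared within an array. Their spread came from the fit of all groups, which includes FAMA 4 h. The median SD within a group was 0.292 there and 0.177 in the 48 h controls. The variance of the 48 h controls alone gave a covariance of 0.0317, below the lowest simulated value of 0.0359. The simulated values are therefore no exact measure of what these shared controls add. Leaving out arrays gave an SE of 0.0055 for the covariance beyond the shared controls, so these values do not decide whether the effects agree. Both inductions raised 91 probe sets and lowered 142, where independent lists would share 33.6 and 45.4. The shared controls add to this agreement by themselves. Both inductions also had estrogen and these controls had none, so a response to estrogen alone would add to it too. Opposite calls were made for 75 probe sets higher with FAMA and lower with FAMA-EAR, against 43.6 for independent lists, and for 73 the other way, against 34.9. Both sets of calls came from the same fit, with the same variance for each probe set. Probe sets with a small variance pass more readily in both, so independent lists understate the overlap of unrelated effects.

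FAMA 48 h was compared with FAMA-EAR 48 h because both had estrogen. The log2 ratio of 3' to 5' probe sets parted these groups furthest, with 0.191 to 0.214 on the FAMA arrays and 0.533 to 0.731 on the FAMA-EAR arrays. EXPA16 was higher with FAMA by 5.98 log2 units (SE 0.145, adjusted p = 5.21e-17) and AT2G34810 by 4.90 (SE 0.118, adjusted p = 5.21e-17). The AP2/ERF gene AT3G57600 was higher by 4.83 (SE 0.223, adjusted p = 1.54e-12) and TET4, a tetraspanin gene, by 4.18 (SE 0.286, adjusted p = 6.62e-10). AT4G15390 (-3.02, SE 0.207, adjusted p = 6.62e-10) and AT1G70820 (-2.29, SE 0.136, adjusted p = 6.63e-11) were lower with FAMA.

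Guard cell genes were higher with FAMA than with FAMA-EAR in 4 of 4 members (4 adjusted over the list alone; median 1.29, adjusted p = 1.27e-05, and 0.0282 with an estimated correlation). PME6 was the weakest of them (0.71, SE 0.246, adjusted p = 0.0432), and its call ended with an offset of 1 (adjusted p = 0.0536), equal array medians (adjusted p = 0.0805), quantile normalization (adjusted p = 0.14) or a replicate block (adjusted p = 0.0544). It also ended without any 1 of the FAMA 48 h arrays (adjusted p = 0.0913 to 0.125) or without the first or second FAMA-EAR array (adjusted p = 0.111 and 0.129), so 3 of the 4 calls held. Lower with FAMA were 2 of 3 stomatal lineage regulators (adjusted p = 0.0121), 3 of 3 Aurora kinase genes (adjusted p = 0.0063) and 5 of 5 photosynthesis genes (adjusted p = 1.27e-05), with the same counts adjusted over the list alone. With an estimated correlation each of these had an adjusted p of 0.0323. The AUR3 call ended without any 1 of the FAMA 48 h arrays (adjusted p = 0.0534 to 0.129) and without the first or second FAMA-EAR array (adjusted p = 0.157 and 0.101), and the AUR2 call without the third FAMA 48 h array (adjusted p = 0.0514). RCA, of the photosynthesis list, stood at -0.003 after quantile normalization (adjusted p = 0.985), and its call also ended with equal array medians (adjusted p = 0.0798) and without the first FAMA-EAR array (adjusted p = 0.0584). Of 7 auxin genes, GH3.5 (WES1) was lower (-0.42, adjusted p = 0.00668; 2 genes adjusted over the list alone) and the list did not pass (adjusted p = 0.115). The XTH family was higher in 4 of 10 members (adjusted p = 0.0163, and adjusted p = 0.145 with an estimated correlation). Of the plastid genes, chosen after their falls on the same FAMA-EAR arrays had been seen, 43 were higher and 3 lower. In all, 2522 probe sets were higher and 2646 lower, 5168 of 22746.

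The controls were compared over time to show what changed without induction, and this comparison joins age with time since transfer. COR15A, a cold-regulated chloroplast protein, fell by 4.28 log2 units (SE 0.309, adjusted p = 3.06e-08), from 1977 ± 266 at 4 h to 87.4 ± 38.0 at 48 h (SD, n = 3 each). The dehydrin LTI30 fell by 1.87 (SE 0.0979, adjusted p = 2.09e-10), COR47 by 1.03 (SE 0.0833, adjusted p = 1.12e-07), and ICL by 2.47 (SE 0.415, adjusted p = 0.00053). AT5G55450, of the lipid transfer protein family, rose by 1.98 (SE 0.259, adjusted p = 3.35e-05). FAMA stood at -0.01 (SE 0.0875, adjusted p = 0.978). The stomatal lineage list was higher at 48 h (adjusted p = 0.00547, and 0.0234 with an estimated correlation), but only 1 of 3 members passed (1 adjusted over the list alone). That member was STOMAGEN, the mesophyll peptide, which rose by 0.80 (SE 0.107, adjusted p = 4.1e-05). The Aurora kinase list was higher too, with 2 of 3 rising (3 adjusted over the list alone; adjusted p = 0.00133, and 0.0211 with an estimated correlation). The AUR2 call was weak: it ended without any 1 of the 48 h controls (adjusted p = 0.0511 to 0.0662), without the first or the third 4 h control (adjusted p = 0.0952 and 0.0577), and with equal array medians, quantile normalization, a floor or no variance trend (adjusted p = 0.0603, 0.0645, 0.053 and 0.066). AUR1 no longer passed without the third 48 h control (adjusted p = 0.0503).

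Early auxin genes were lower at 48 h, with 2 of 7 past the threshold (2 adjusted over the list alone; adjusted p = 0.00261, and 0.0234 with an estimated correlation), of which IAA29 no longer passed without the first or the third 4 h control (adjusted p = 0.0775 and 0.0588) or the first 48 h control (adjusted p = 0.0818). Photosynthesis genes had a median of 0.24, 0 of 5 past the threshold in limma and 3 adjusted over the list alone (adjusted p = 0.0105, and adjusted p = 0.203 with an estimated correlation). The median of that list was 0.12 after quantile normalization (adjusted p = 0.371), and the 230 other bright probe sets had a median of 0.14 before it. The UGT family of glycosyltransferases was lower, with 9 of 51 members falling (adjusted p = 0.000481, and adjusted p = 0.259 with an estimated correlation). Of 22746 probe sets, 767 were higher and 866 lower at 48 h, 1633 in all. The count was 1041 without the second 48 h control, 941 with no variance trend, 2653 with array weights and 174 with a test without moderation. Of the 69 plastid genes 13 fell and 0 rose (22 fell adjusted over the list alone), with a median of -0.34 (adjusted p = 2.19e-13, and adjusted p = 0.155 with an estimated correlation).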

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

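The tests of the third FAMA 4 h array and of the plastid genes, and those of the transcript level and the opposite movement in FAMA-EAR, were chosen only after the results were seen. The test of spread between FAMA-EAR arrays and the counts of other splits were set before.

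The effect of FAMA differed between 48 h and 4 h in 3103 probe sets by a test of the difference itself, which set this result apart. It was 3467 without the third FAMA 4 h array and 929 with at least a 2-fold difference. Among 100 drawn splits of the arrays within each time, the real split was the 1 with this many, and the highest other gave 2993. That split kept the real 48 h groups, as 11 of the drawn ones did, and the highest of the rest gave 4. Splits of this kind show that the FAMA 48 h groups part from each other, and say little about the difference between times.

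Probe sets for bacterial genes, which no plant RNA matches and which the comparisons do not use, had a median signal of 50.4 on the third FAMA 4 h array, above the highest other array at 10.4. That array also had the highest median signal, 239.5, and an array weight of 0.146 against 0.631 to 1.94 on the others. A label swapped with an uninduced sample was argued against, since FAMA read 11695.5 there and at most 255.7 in the controls. Degraded RNA was argued against too, since its log2 ratio of 3' to 5' probe sets was 0.376, within the range of the others, which reached 0.731. Raised background on this array remains a candidate explanation; no biological explanation was tested.

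FAMA-EAR changed 729 probe sets and FAMA 4913 at 48 h, over the same controls. Larger spread between the FAMA-EAR arrays was argued against: judged by the spread of the FAMA-EAR and control 48 h arrays alone, 4993 probe sets passed for FAMA and 677 for FAMA-EAR. A movement of FAMA's genes in the opposite direction over all probe sets cannot be told apart from none: the covariance of both effects exceeded that from the variance of the shared controls by 0.0107, less than 2 SE from leaving out each array (0.0055), though it stayed above 0 with any 1 array left out (0.00568 to 0.0133), and exceeded the mean of simulated shared controls by 0.005. The simulated mean, 0.0374, used the spread of all groups and lay above the 0.0317 from the variance of the shared controls. Both inductions also had estrogen and the controls had none, so the covariance of both effects may hold a response to estrogen. A lower level of the induced transcript may account for the smaller count, since the highest FAMA signal of a FAMA-EAR array was 3456.5 and the lowest of a FAMA 48 h array 16934.1. The design joins that level with the EAR fusion itself, and an effect of the fusion stays open and untested.

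Plastid-encoded transcripts were lower in FAMA-EAR seedlings, with a median of -0.98 over 69 genes. A lower share of green tissue was argued against, for the 5 nuclear photosynthesis genes measured. Their median was 0.042, where a value of -0.491 or lower was needed. The SE used there, 0.049, was taken across these 5 genes and not across arrays. More degraded RNA could contribute, since the lowest log2 ratio of 3' to 5' probe sets on a FAMA-EAR array was 0.533 and the highest on the other 48 h arrays 0.496. This ratio is a mean of actin and GAPDH, and GAPDH alone did not part every FAMA-EAR array from every 48 h control. A uniform loss of RNA without poly(A) tails during labelling had been left open by a first test. In it 17 of 69 genes lay clearly above -0.491, just under the share set as the bound. A later test argued against equal log2 falls, because 40 of 69 genes differed from the group's median by more than 2 SE, where 4.1 were expected if all fell alike. Genes with higher control signals fell less (Spearman correlation 0.328), so that count cannot decide on a uniform loss that bright probe sets read less fully. An uneven loss of such RNA and a lower plastid transcript level through the FAMA-EAR protein stay open and untested. The 16 mitochondrial genes, whose RNA also lacks stable tails, decided neither. Of these, 10 lay near background, and the 6 with control signals over 100 had a median of -0.34 (SE across the 6 genes 0.093).

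The splits of 3 arrays against 3 number 10, too few for a share under 0.05. The real counts and the highest of the other splits were 664 and 1 for FAMA at 4 h, 4913 and 0 for FAMA at 48 h, 729 and 1 for FAMA-EAR, 5168 and 0 for FAMA against FAMA-EAR, and 1633 and 0 for the controls over time.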

How the results depend on the processing

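Results without the third FAMA 4 h array beyond its own comparisons, and those of the name families and the plastid group, were chosen only after the data were seen. No fold change of FAMA reversed, and of 362 results for named genes 203 passed, 0 reversed, 119 lost their call in some setting, and 43 did so outside the 2-fold and unmoderated settings. The cause was not tested where a setting moved a value, except that the 2-fold threshold and the unmoderated test are stricter by construction. Signal over background limits genes near the offset of 20, and 3 arrays per group limit the rest. The Pearson correlation of FAMA effects at 4 h and 48 h changed sign to -0.0268 at an offset of 1, and was 0.101 with the median divided by 2 as the offset, 0.0901 with a floor and 0.144 above the 40th percentile. That of FAMA and FAMA-EAR was 0.355 at an offset of 1 and 0.134 above the 40th percentile. Equal array medians gave 463 probe sets for FAMA-EAR. No variance trend gave 303 for FAMA at 4 h, 322 for FAMA-EAR and 941 for the controls. Array weights gave 1217 for FAMA-EAR and 2653 for the controls. A fit of only the groups compared gave 207 at 4 h. Replicate number as a block gave 649 at 4 h, 4901 at 48 h, 749 for FAMA-EAR, 5218 for FAMA against FAMA-EAR, 3091 for the difference and 1653 for the controls; residuals of same-numbered arrays correlated by -0.061 to 0.042 between groups, so the numbers did not pair the samples. A per-gene test without moderation gave 2 at 4 h (2006 with unadjusted p under 0.05), 0 for FAMA-EAR (3181 unadjusted; 729 with limma) and 174 for the controls (3992 unadjusted), and FAMA in FAMA-EAR, at 3.54, did not pass; this test was not run for the difference between times. With at least a 2-fold change the counts were 116, 851, 156, 1057, 929 and 253 for FAMA at 4 h, FAMA at 48 h, FAMA-EAR, FAMA against FAMA-EAR, the difference and the controls; this threshold does not apply to lists or correlations. For the difference between times, 3 lists passed as reported, 0 with an estimated correlation and 5 with fry.

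Leaving out 1 array at a time gave 342 to 1077 probe sets for FAMA at 4 h, 3844 to 5830 at 48 h, 358 to 1176 for FAMA-EAR, 4094 to 6154 for FAMA against FAMA-EAR, 2448 to 3467 for the difference and 1041 to 2264 for the controls. The highest values at 48 h, for FAMA-EAR, for FAMA against FAMA-EAR, for the difference and for the controls came without the third FAMA 4 h array. Lists numbered 0 to 0, 5 to 5, 0 to 1, 4 to 4 and 2 to 5 for FAMA at 4 h, at 48 h, FAMA-EAR, FAMA against FAMA-EAR and the difference. The correlations ranged from 0.02 to 0.07 for the times and from 0.23 to 0.33 for FAMA and FAMA-EAR. The log2 fold change of FAMA ranged from 5.50 to 5.58 at 4 h, 6.06 to 6.14 at 48 h, 3.45 to 3.62 for FAMA-EAR and 2.48 to 2.65 between both constructs. An array left out leaves 2 in its group.

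With an estimated correlation 0 families passed for FAMA at 4 h, FAMA at 48 h, FAMA-EAR, FAMA against FAMA-EAR and the controls, and 1 for the difference. At 4 h 0 passed after quantile normalization or without the third FAMA 4 h array, and without it 2 passed for FAMA against FAMA-EAR. The plastid median at 4 h was -0.08 and no longer passed with an estimated correlation (adjusted p = 0.341) nor after quantile normalization (-0.05). Quantile normalization otherwise left counts within 1.5 times of those reported, with 644, 4677, 654, 5013, 3020 and 1553.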

Other observations

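The genes in this part, and the group they belong to, were chosen only after the values had been seen. BHLH101 and AT1G47400, both genes of the iron deficiency response, were called in opposite directions under both constructs at 48 h. AT1G47400, which encodes a small peptide of iron signalling, rose by 2.68 with FAMA (SE 0.18, adjusted p = 4.7e-10), from 633.7 ± 62.5 to 4182 ± 735 (SD, n = 3 each), and fell by 0.81 with FAMA-EAR (SE 0.18, adjusted p = 0.012). The transcription factor gene BHLH101 rose by 2.18 and fell by 1.68 (SE 0.28, adjusted p = 0.001). Its signal was 99.77 ± 18.8 in the 48 h controls and 19.07 ± 14.6 with FAMA-EAR (SD, n = 3 each), near background, so the size of the fall depends on the offset. Of 2 further measured genes of this response, PYE rose by 0.64 with FAMA and stood at -0.27 with FAMA-EAR (adjusted p = 0.35), and AT3G12900 stood at -0.999 with FAMA (SE 0.51, adjusted p = 0.2) and at -0.09 with FAMA-EAR. Tests of the 4 as a group would restate the calls that led to it, and are not given here.

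Other genes were called in opposite directions. For all such calls, the log2 ratio of 3' to 5' probe sets for actin and GAPDH also moved opposite ways. That ratio lay lower on every FAMA 48 h array and higher on every FAMA-EAR array than on each 48 h control. Whether it played a part in these calls was not tested. EXPA16 rose by 4.86 with FAMA and fell by 1.11 with FAMA-EAR (adjusted p = 9e-05), and AT5G20790 rose by 2.46 and fell by 0.67 (adjusted p = 0.045). AT4G15390 fell by 2.2 with FAMA and rose by 0.83 with FAMA-EAR (adjusted p = 0.03), AT1G70820 fell by 1.5 and rose by 0.79 (adjusted p = 0.0016), and AT3G62550 fell by 1.01 and rose by 1.1 (adjusted p = 0.00095). Some transcripts moved early and then back under FAMA: PMEPCRF, a pectin methylesterase gene, fell by 0.71 at 4 h and rose by 2.61 at 48 h (adjusted p of the difference 2.4e-11), and PORB, of chlorophyll synthesis, rose by 0.41 and fell by 0.71 (adjusted p of the difference 2.9e-05). BCAT4, of glucosinolate synthesis, rose by 0.79 at 4 h and fell by 0.45 at 48 h (adjusted p of the difference 9.1e-06).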
